A study of Mus musculus with 100 samples.

How the data were processed

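Messenger RNA of mouse fat and of adipocytes was sequenced from stranded poly(A) libraries, per the labels' protocols. Samples were grouped by the tissue, age, treatment and genotype given in their labels; the genotype stands only in the titles, since the strain label is the same for wild type and knockout. Of 100 samples in the series 99 were used, each matched to 1 column by name. A further 1 column, of the adipocyte table and named as wild type, matched no sample and was not used. The third sample labelled knockout of that table was not analysed here. Whether that column belongs to it is not given.

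The deposited values are a signal per Ensembl transcript, namely read counts divided by a size factor for each library. The submitters' processing notes name bcl2fastq 2.17, STAR 2.4.0k, SAMtools, HTSeq 0.5.3 and DESeq 1.8.3 and the build GRCm38.p4, with no role or setting, and whether counting used the strand is not given in the sources used here. In all 99 libraries the deposited signal divided by its smallest step gave whole numbers for 100% of values, within a tolerance of 0.01 of a read. In 96 libraries these were taken as recovered reads. In 3 libraries, 1 each of BA wild type 4, HFD knockout 2 and HFD wild type 4, they were not. A read can be listed under each isoform it overlaps, so 1 transcript was taken per gene, that with the highest mean among the transcripts of the gene's own type. Of 97669 transcripts over all tables, 698 had no gene in GENCODE M21 on GRCm38, which also gave symbols and positions, and they held 0.333% of the values. There were 32484 genes with a chosen transcript after 54 identifiers with the symbol of another gene were dropped. For 6.00% of genes more than 50% of the chosen transcript overlapped exons of another gene; reads of such overlapping or antisense genes cannot be told apart here.

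The 5 tables were normalised separately, so wild type and knockout were tested only within a table, and levels in different tables are not on 1 scale. Libraries of the same group and replicate that differed only in a leading number were compared by a chi-square test over genes with 50 reads or more, differed by about the sampling noise and were averaged to 1 replicate. The libraries labelled CD knockout 1 and 2 were closer to each other than other CD pairs (chi-square per degree of freedom 6.76, against 161 to 1101), but beyond that noise (at most 1.10 within a replicate), and were kept apart. No label says that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

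Because the values are normalised and not counts, the main test was limma 3.58.1 in R 4.3.3, with trend and robust moderation, on log2(value + 1) of genes with a mean value of 10 or more, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Differences in the effect of genotype between 2 tables were tested as an interaction in 1 fit, where both were normalised separately. The numbers of the Epi and Adipo samples were checked for pairing by the correlation of deviations from the group means: all 5 same-numbered pairs lay above 0.1, from 0.293 to 0.595 in wild type and at 0.106 and 0.269 in the libraries labelled knockout. The recovered reads were tested with the quasi-likelihood test of edgeR 4.0.16 and with DESeq2 1.42.0, as alternatives chosen after the data were seen.

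The design, the alternatives listed below except where noted, the rule for named genes and 38 gene lists covering metabolic pathways, stress responses and cell-type markers were fixed before the data were examined. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move, on balance, 1 way. Named genes were Gps2, the 10 higher and 10 lower genes of largest log2 fold change among those that passed with a mean of 50 or more and no overlap between groups (leaving out predicted, pseudogene, immunoglobulin and T cell receptor genes), and up to 4 members of each list that passed. Where no member passed, up to 2 were named as values, and where no gene passed, the 5 higher and 5 lower of smallest p; for each difference between tables there were up to 5 of either sign. Results on some single genes are not reported here. The alternatives were TMM scaling, no trend or robust moderation, no filter, a minimum of 50, pseudocounts of 0.5 and 5, the replicate number as a block, each of the leading numbers alone, a size threshold of 1 on the log2 scale, and each replicate left out. Shares of Gps2 reads carry 95% Clopper-Pearson intervals in the tables, which cover counting error only.

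Limma was tested on simulated data with 200 changed genes in each table and for HFD against CD, edgeR and DESeq2 for HFD and BA, and camera for HFD. Limma recovered 73% of genes changed by 1 on the log2 scale and 91% of those changed by 2 for HFD (14254 genes), 1% and 41% for CD (16057), 21% and 51% for Epi (18458), 34% and 69% for Adipo (14538) and 69% and 96% for BA (12484). For the difference between HFD and CD it recovered 20% and 68% (15056 genes). DESeq2 also called 47 unchanged genes for HFD and 46 for BA, where limma called 4 and 8. The simulated noise was drawn independently for each gene and sample. It thus lacks differences that many genes of a library share, such as RNA of other tissues. These rates need not hold in the real tables. Other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.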

Results

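RNA sequencing of mouse fat was used to ask which genes are deregulated when GPS2, a subunit of the NCoR/SMRT corepressor complex, is lost from adipocytes, on normal chow, on high fat diet and under beta-adrenergic stimulation. The 99 libraries used fell into 5 tables, each with libraries labelled wild type and libraries labelled adipocyte knockout (Gps2 floxed alleles with Adipoq-Cre). The CD table held intra-abdominal fat of mice on normal chow aged 19 weeks (3 wild type, 3 knockout). The HFD table held intra-abdominal fat of mice on high fat diet aged 11 weeks (4 and 4), with 4 weeks of diet in the table's name. The Epi table (3 and 3) and the Adipo table (3 and 2) held intra-abdominal fat and intra-abdominal adipocytes at 19 weeks, with 12 weeks of high fat diet in their names. The BA table held inguinal fat of the beta-adrenergic series at 8 weeks (4 and 4). In the CD, HFD and BA tables each replicate had 4 libraries that differed from each other by about the sampling noise and were counted as 1 sample. Recovered reads per replicate, summed over the transcript chosen for each gene, ranged from 47839089 to 56772573 in CD, 41912401 to 63456837 in HFD and 42825842 to 58581144 in BA. They ranged from 29444602 to 58775445 in Epi and 36792112 to 44742965 in Adipo. The lowest sums of HFD and BA, both of wild type 4, cover 3 of the 4 libraries, as does that of HFD knockout 2.

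Gps2 itself (ENSMUSG00000023170, chromosome 11, 69913888 to 69916591, plus strand, GRCm38) was measured first. Its full-length transcript, with 10 exons, was not lower in any table, though in CD its log2 fold change was -0.07 after TMM scaling. It stood at 585 ± 117 normalised reads in wild type and 597 ± 58.0 in the libraries labelled knockout in CD (SD, n = 3 and 3), at 388 ± 27.1 and 390 ± 42.7 in HFD (n = 4 and 4), and at 1222 ± 237 and 1316 ± 103 in Epi (n = 3 and 3). In Adipo it was 803 ± 47.7 and 825 ± 20.1 (n = 3 and 2), and in BA 286 ± 60.5 and 315 ± 46.8 (n = 4 and 4). The log2 fold changes were 0.04 ± 0.18 (SE) in CD, 0.01 ± 0.10 in HFD, 0.12 ± 0.16 in Epi, 0.04 ± 0.13 in Adipo and 0.15 ± 0.17 in BA. The deleted exons are not given in the sources used here, and reads of a transcript that keeps its other exons check nothing, so the genotype below is always that of the label. A short transcript of 5 exons covers only the region from 69914845 to 69915880. Its reads as a percent of those of the full-length transcript, called the short share here, were compared after the values had been seen. That share was 45.0 ± 2.45% in wild type and 32.9 ± 2.44% in the libraries labelled knockout in BA (SD, n = 4 and 4; exact two-sided permutation p = 0.0286). It was 40.4 ± 3.98% and 35.1 ± 0.945% in HFD (n = 4 and 4, exact permutation p = 0.0571) and 42.5 ± 3.32% and 34.5 ± 5.05% in CD (n = 3 and 3, exact permutation p = 0.1, the smallest that 3 against 3 allow). In Epi it was 46.4 ± 3.60% and 46.2 ± 6.67% (n = 3 and 3, exact permutation p = 1), with the library labelled knockout 1 at 38.5% and those labelled knockout 2 and 3 at 50.3% and 49.9%. In Adipo it was 48.8 ± 2.92% and 39.6 ± 11.7% (n = 3 and 2, exact permutation p = 0.4), with the libraries labelled knockout 1 and 2 at 31.3% and 47.9%. The share in the libraries labelled Epi knockout 2 and 3 and Adipo knockout 2 thus lay within or above the range of the wild-type libraries. That in the library labelled HFD wild type 4, at 35.3%, lay within the range of 34.2% to 36.3% of the HFD libraries labelled knockout. In the library labelled CD knockout 2 it was 39.7%, next to the lowest CD wild-type share of 40.2%. Over all 5 tables, with the labels permuted within each table and each sample taken as independent, the mean log2 difference of the share was -0.261 (permutation p = 0.00015). However, same-numbered Epi and Adipo samples deviated together, and the libraries labelled CD knockout 1 and 2 were nearly alike. That permutation p may thus be too small. Whether the share reads the deletion was not tested.

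**Figure D1:**
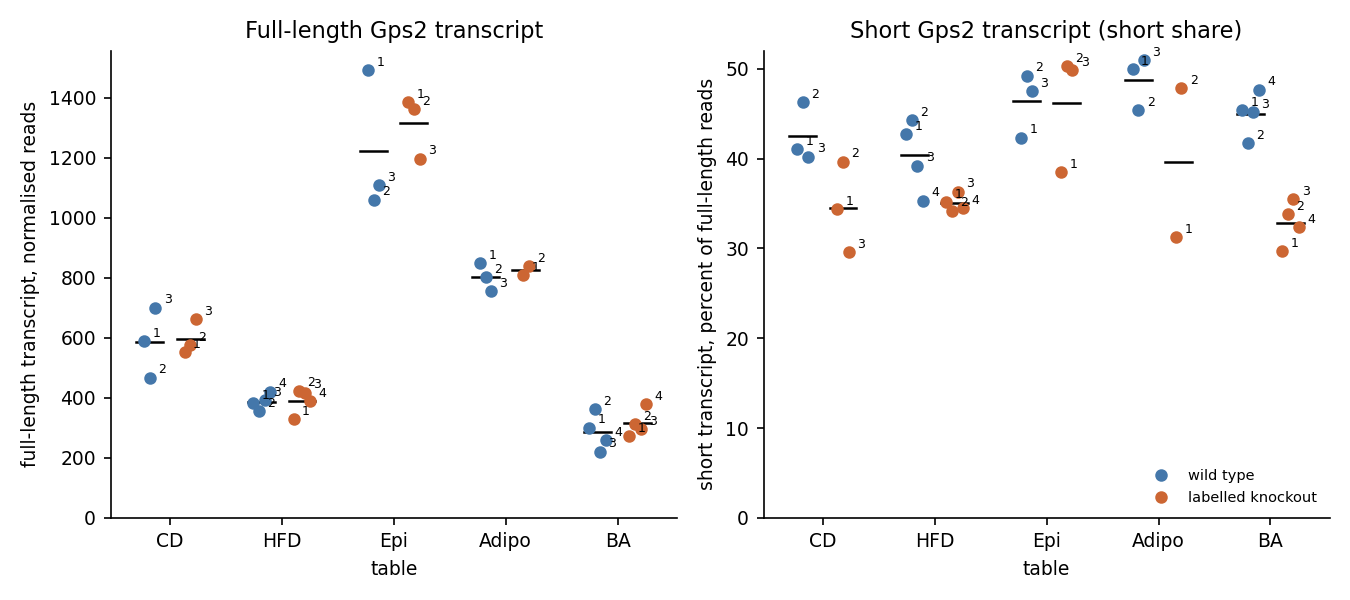
Left, normalised reads of the full-length Gps2 transcript per replicate in the 5 tables; right, reads of the short transcript as a percent of those of the full-length one. Points are replicates with their number, black lines are group means; the libraries labelled knockout lie at 29.7% to 35.5% in BA, below the wild-type range of 41.7% to 47.7%.

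In intra-abdominal fat on high fat diet (HFD table), 142 genes rose and 344 fell in the libraries labelled knockout. Among those that rose most, Cyp2f2, a cytochrome P450 (chromosome 7, 27119909 to 27133660), rose from 57.2 ± 50.05 to 1352 ± 909 normalised reads (SD, n = 4 and 4; log2 fold change 4.62 ± 0.66 SE). Prlr, the prolactin receptor (chromosome 15, 10177238 to 10349180), rose from 205.4 ± 35.9 to 849 ± 232 (2.02 ± 0.21). Insig1, which holds back the maturation of sterol-regulated transcription factors, rose from 2352 ± 985 to 7077 ± 920 (1.68 ± 0.28). Sfrp5, a secreted Wnt antagonist (chromosome 19, 42197971 to 42202252), fell from 2536 ± 1704 to 85.4 ± 59.1 (-4.76 ± 0.77). Synpo2, an actin-binding protein (chromosome 3, 123076519 to 123236149), fell from 2955 ± 922 to 362 ± 25.5 (-2.98 ± 0.19). The imprinted gene Nnat fell from 36110 ± 17400 to 7053 ± 1806 (-2.27 ± 0.31) and Kcnk3, a potassium channel, from 824 ± 248 to 135 ± 29.3 (-2.58 ± 0.25).

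By limma with Benjamini-Hochberg adjustment over 14069 genes, the adjusted p was 0.000688 for Synpo2, 0.00229 for Kcnk3, 0.00237 for Prlr, 0.00668 for Nnat and 0.00791 for Cyp2f2. By the same limma test it was 0.0133 for Sfrp5 and 0.0138 for Insig1. Other genes of largest change that rose included Serpina3b, Shisa6, Pnpla5, Nabp1 and Mogat2, with log2 fold changes from 1.63 to 2.79. The others that fell were Oxtr (-2.46 ± 0.41), Efcab8, Adamtsl2, Bcat1, Ncan and Dok7. Serpina3b belongs to a family of close copies that can share reads and is uncertain. After TMM scaling 218 genes rose and 313 fell, 419 of the 531 shared with the 486 above. edgeR on the recovered reads called 540 genes (408 shared) and DESeq2 called 1538. Without the library labelled wild type 1, 3 or 4 the count was 1178, 307 or 282. Without that labelled knockout 1, 2, 3 or 4 it was 182, 262, 148 or 126.

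**Figure D2:**
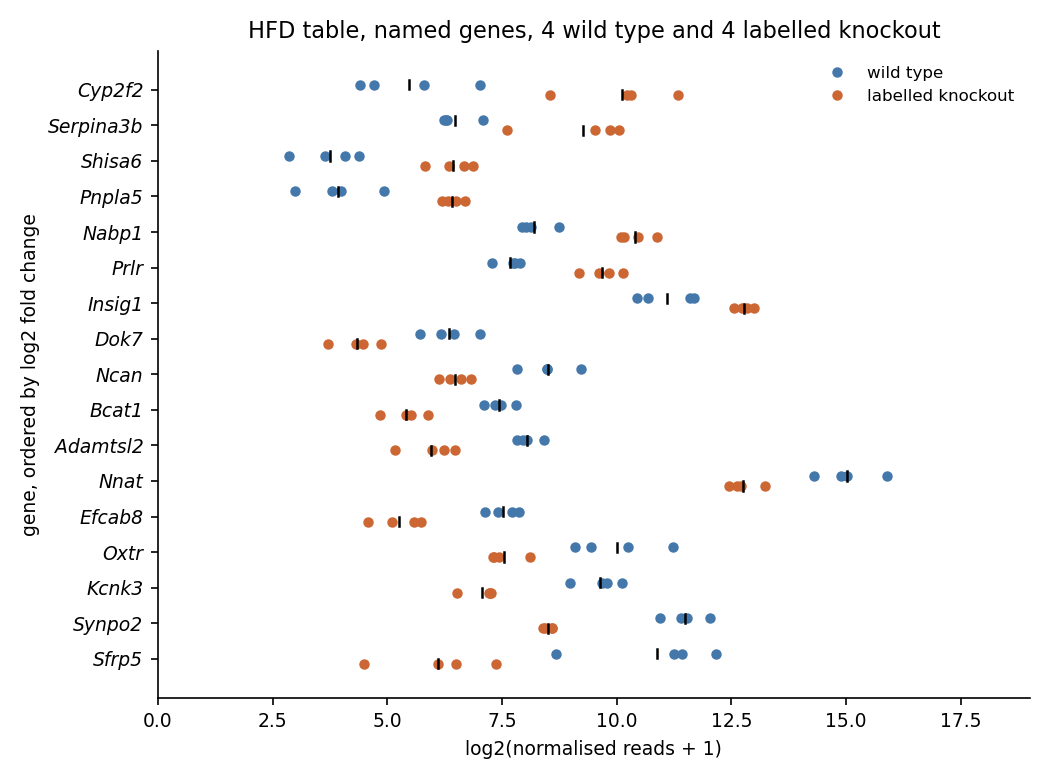
Genes among those with the largest rise or fall in the HFD table that had an adjusted p under 0.02 (limma, Benjamini-Hochberg), as log2(normalised reads + 1) per replicate on the horizontal axis. Points are replicates and black lines are group means (n = 4 and 4); the 2 groups do not overlap for any of these genes, which were chosen for that among other criteria.

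Of the lists fixed beforehand 21 of 37 had at least 1 member that passed in the HFD table, with 23 memberships that rose and 19 that fell. Camera called 12 of 37 lists, 12 higher and 0 lower, and 0 with an estimated correlation. Of 18 adipocyte identity genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), namely Acsl1 (log2 fold change 0.90 ± 0.16 SE), the adipogenic regulator Pparg (0.63 ± 0.12) and Cfd, or adipsin (0.97 ± 0.22). Of 20 genes of the early cAMP response 3 rose and 1 fell (7 and 1 adjusted over the list alone). The insulin receptor substrate Irs2 rose from 1028 ± 64.8 to 2078 ± 215 (SD, n = 4 and 4). Gadd45g rose by 1.38 ± 0.14 and the thyroid hormone deiodinase Dio2 by 1.93 ± 0.42 on the log2 scale, while the phosphodiesterase Pde4d fell by 1.18 ± 0.17. That list was called higher by camera (adjusted p = 0.000877), but adjusted p = 0.911 with an estimated correlation. Of 19 thermogenic genes 1 rose (Dio2) and 3 fell, Kcnk3, Cox7a1 (-1.59 ± 0.34) and Pdk4 (-0.73 ± 0.10). There were 3 and 8 adjusted over the list alone. Among 11 LXR targets the cholesterol exporter Abcg1 fell from 731 ± 152 to 273 ± 28.7 and Apoc1 fell by 0.82 ± 0.19 on the log2 scale (0 rose and 2 fell; 1 and 2 adjusted over the list alone). Of 17 lipolysis and lipid droplet genes 2 fell, the beta-adrenergic receptor Adrb1 (-1.04 ± 0.19) and the glycerol channel Aqp7 (-0.58 ± 0.13). Of 19 lipogenic genes 1 fell, Acacb (-0.80 ± 0.14), while 14 were higher and 4 lower without passing, with a median of 0.20. Camera called the lipogenic list higher (adjusted p = 0.0195, but adjusted p = 0.911 with an estimated correlation). Adjusted over the list alone these lists had 1 up and 2 down, and 2 up and 1 down. Among mitochondrial biogenesis genes the coactivator Ppargc1b rose from 24.6 ± 4.27 to 60.8 ± 6.67. By contrast, 0 of 73 nuclear-encoded OXPHOS genes passed the limma test, 0 adjusted over the list alone, with a median log2 fold change of -0.11.

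In the same HFD libraries 3 of 31 extracellular matrix genes fell, Col18a1 (log2 fold change -0.63 ± 0.12 SE), Thbs2 (-1.55 ± 0.31) and Col6a1 (-0.57 ± 0.12). Of the others 17 were higher and 11 lower without passing, and the list had a median of 0.05. Of 34 HIF1A and glycolysis genes 3 rose and 2 fell, with Ddit4 (0.96 ± 0.08) and Pfkfb3 (0.54 ± 0.11) among those that rose. Adjusted over the list alone the counts were 0 up and 3 down, and 4 and 4. Antioxidant genes moved both ways, with Gsta3 (1.06 ± 0.13) and Gclc (0.52 ± 0.11) up and Gpx3 (-1.21 ± 0.23) down (3 and 2 adjusted over the list alone). The endothelial transcription factor Sox18 (-1.33 ± 0.15) and the macrophage receptor Mertk (-0.65 ± 0.14) fell. Of 22 macrophage markers only Mertk passed, while 19 were higher and 2 lower without passing, with a median of 0.31. Camera called that list higher (adjusted p = 0.000317, but adjusted p = 0.911 with an estimated correlation). The NF-kB feedback gene Tnfaip3 (1.06 ± 0.13), the chemokine Cxcl9 (0.91 ± 0.15) and the stromal list member Gsn (0.91 ± 0.18) rose. All 13 measured B cell markers were higher without passing, with a median of 0.95. Their mean log2 level was 6.22 in the library labelled knockout 1 against 4.03 to 4.34 in the other 3. Epithelial markers stood at 7.02 in the library labelled wild type 1 against 3.53 to 4.70 in the other wild-type libraries. Of the 55 named genes that passed, 55, 47, 39 and 36 passed without the library labelled wild type 1, 2, 3 and 4. Without that labelled knockout 1, 2, 3 and 4 the numbers were 29, 34, 24 and 23, all 55 in the same direction each time. Without the libraries labelled wild type 1 and knockout 1 together 448 genes were called, 305 of them shared.

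In intra-abdominal fat on normal chow (CD table), the values of cholesterol synthesis genes lay higher and those of mast cell genes lower in the libraries labelled knockout, but 0 of 15617 genes passed limma with Benjamini-Hochberg adjustment. Acat2, the cytosolic thiolase of cholesterol synthesis, was 720 ± 223 normalised reads in wild type and 2350 ± 207 in the libraries labelled knockout (SD, n = 3 and 3; log2 fold change 1.74 ± 0.23 SE). The sterol oxidase Msmo1 was 330 ± 106 and 1032 ± 126 (1.68 ± 0.24). The mast cell proteases Tpsb2 and Mcpt4 were 223 ± 25.0 and 145 ± 13.6 in wild type and 47.1 ± 9.84 and 32.5 ± 8.25 in the libraries labelled knockout (-2.23 ± 0.24 and -2.15 ± 0.27). The beta-adrenergic receptor Adrb1 was 60.2 ± 4.08 and 19.3 ± 1.51 (-1.59 ± 0.27). Other genes of smallest p were Zfp949 (1.79 ± 0.22), Tecr, an enzyme of fatty acid elongation (1.37 ± 0.19), Eif4a2 (1.01 ± 0.15) and Sdr42e1 (0.88 ± 0.12) on the higher side. On the lower side they were Dok7 (-1.69 ± 0.22), the insulin receptor adaptor Grb14 (-1.51 ± 0.22) and Kctd15 (-1.06 ± 0.15).

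Of 22 cholesterol synthesis genes all 22 were higher in CD, 0 passed over all genes and 13 passed adjusted over the list alone. Their median log2 fold change was 1.08 (camera adjusted p = 3.43e-10, but adjusted p = 0.235 with an estimated correlation; fry adjusted p = 0.0328). All 19 lipogenic genes were higher, 0 over all genes and 6 adjusted over the list alone, with a median of 1.06 (camera adjusted p = 9.47e-06, adjusted p = 0.630 with an estimated correlation). The desaturase Scd2 was 2963 ± 2295 and 14390 ± 1047 (SD, n = 3 and 3). Of 73 nuclear-encoded OXPHOS genes 72 were higher, 0 over all genes and 1 adjusted over the list alone (Ndufa1). Their median was 0.45 (camera adjusted p = 1.36e-10, adjusted p = 0.666 with an estimated correlation). Of 16 antioxidant genes 15 were higher, with a median of 0.60 (camera adjusted p = 0.000690, adjusted p = 0.235 with an estimated correlation). Of 6 measured mast cell markers 5 were lower, 0 over all genes and 5 adjusted over the list alone, with a median of -2.19 (camera adjusted p = 7.82e-08, adjusted p = 0.235 with an estimated correlation). Macrophage markers were lower for 20 of 22 (median -0.53), extracellular matrix genes for 23 of 31 (-0.35) and B cell markers for 16 of 16 (-1.33). The library labelled wild type 1 stood highest for all 3 lists, at 9.42, 11.06 and 7.68 on the log2 scale. For B cell markers those labelled wild type 2 and 3 were at 4.69 and 3.37 and those labelled knockout at 3.61 to 4.75. In these lists 0 members passed over all genes or adjusted over the list alone. Their camera adjusted p was 2.50e-07, 9.47e-06 and 0.000200, against 0.630, 0.630 and 0.666 as adjusted p with an estimated correlation. Camera called 21 of 38 lists, and 13 without the library labelled wild type 2. TMM scaling shifted the median log2 fold change of all genes from 0.11 to 0.00, and each list median above by about as much, with no change of direction.

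At an unadjusted p under 0.05 there were 1506 genes in CD where limma called 0, edgeR called 0 and DESeq2 918. The libraries labelled knockout 1 and 2 were nearly alike and n = 3 counts them apart, as the labels do; whether they come from 1 animal is not given. Taken as 1 replicate they left 497 genes at an unadjusted p under 0.05 and 0 called by limma. Limma called 648 without the library labelled knockout 3, which leaves only that nearly alike pair in the arm. Their spread may be too small, so that count may be too high. The libraries labelled knockout 1 and 2 carried epididymis and testis markers, 11 of 17 at 50 normalised reads or more (Adam7, an epididymal gene, at 29590 and 28660), against 0 in the library labelled knockout 3. Mammary and epithelial markers had a mean log2 level of 9.18 in the library labelled wild type 2 and 9.14 and 9.09 in those labelled knockout 1 and 2, against at most 3.62 in the other 3. Skeletal muscle markers stood at 8.53 in the library labelled wild type 2 against 4.10 to 5.08 in the others.

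In the Epi table, intra-abdominal fat of the longer diet, cell cycle and extracellular matrix genes had lower values in the libraries labelled knockout, again with 0 of 17685 genes past limma with Benjamini-Hochberg adjustment. The proliferation marker Mki67 was 1593 ± 304 normalised reads in wild type and 598 ± 135 in the libraries labelled knockout (SD, n = 3 and 3; log2 fold change -1.42 ± 0.22 SE). The ribonucleotide reductase subunit Rrm2 was 481 ± 56.2 and 187 ± 17.3 (-1.36 ± 0.19). Bmp3, a bone morphogenetic protein, was 3157 ± 725 and 861 ± 164 (-1.87 ± 0.21). The neutrophil gene S100a8 was 318 ± 164 and 30.5 ± 6.87 (-3.25 ± 0.43). On the higher side Axin2, a Wnt target gene, was 503 ± 63.9 and 1763 ± 549 (1.77 ± 0.23). The fatty acid desaturase Fads1 was 2449 ± 174 and 6459 ± 1777 (1.36 ± 0.22). Gpc1 (-1.03 ± 0.11), Plppr4 (-2.58 ± 0.31), Crtac1 (-1.36 ± 0.18), Hs3st3b1 (2.46 ± 0.41) and Acad10 (0.77 ± 0.14) were the others of smallest p. Grcc10 (0.83 ± 0.13), also among them, shares 54% of its chosen transcript with exons of another gene and is uncertain.

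Of 21 cell cycle genes all 21 were lower in Epi, 0 passed over all genes and 14 passed adjusted over the list alone. Their median log2 fold change was -1.33 (camera adjusted p = 9.34e-15, but adjusted p = 0.824 with an estimated correlation). Extracellular matrix genes were lower for 29 of 31, with 0 over all genes and 11 adjusted over the list alone and a median of -0.60 (camera adjusted p = 6.60e-09, adjusted p = 0.824 with an estimated correlation), among them Fbn1 (-0.98 ± 0.20 SE) and the cross-linking enzyme Lox (-0.61 ± 0.13). All 73 nuclear-encoded OXPHOS genes were higher, 0 over all genes and 0 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 1.75e-11, adjusted p = 0.838 with an estimated correlation). Their mean log2 level was 12.99, 12.30 and 12.62 in the libraries labelled knockout 1, 2 and 3 and 12.31, 12.46 and 12.18 in wild type. Adipocyte identity genes stood at 17.1, 16.4 and 16.9 against 16.7, 16.8 and 16.3. Cytokine and NF-kB genes were lower for 27 of 30 (median -0.44; Ccl2 746 ± 570 and 133 ± 30.9, SD, n = 3 and 3) and interferon genes for 22 of 25 (median -0.27). Camera adjusted p was 0.000307 and 0.00330 against adjusted p of 0.824 and 0.838 with an estimated correlation. The library labelled wild type 3 stood highest for both lists (9.71 against 8.97 and 8.82 in the other wild-type libraries, and 10.06 against 9.61 and 9.48) and for macrophage markers (11.81 against 10.89 and 10.85). Without it the interferon levels overlap those of the libraries labelled knockout, 9.24 to 9.55. Epididymis and testis markers were higher for 14 of 16 measured, with a median of 4.32. Of the 17, 16 and 14 stood at 50 normalised reads or more in the libraries labelled knockout 2 and 3, 0 in that labelled knockout 1 and 6 in that labelled wild type 1. At an unadjusted p under 0.05 there were 1626 genes where limma called 0, edgeR called 0 and DESeq2 528. Limma called 22 without the library labelled knockout 1 and 1 without that labelled knockout 2. The directions follow the labels, though the short share of Gps2 lay above wild type in the libraries labelled knockout 2 and 3.

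In adipocytes of the longer diet (Adipo table), 77 genes rose and 13 fell in the 2 libraries labelled knockout against 3 wild-type libraries (limma, Benjamini-Hochberg, 14248 genes). Socs3 rose from 551 ± 304 to 14250 ± 1482 normalised reads (SD, n = 3 and 2; log2 fold change 4.90 ± 0.57 SE), the stress factor Atf3 from 1689 ± 258 to 22910 ± 6929 (3.74 ± 0.23) and Nfkbiz from 1150 ± 418 to 15890 ± 3467 (3.83 ± 0.32). The largest rises were those of Rgs16 (5.60 ± 0.53) and Rnd1 (4.95 ± 0.32), followed by Egr2, Apold1, Arid5a, Sox17 and Fosb among the genes of largest change. The heat shock genes Hspa1a and Hspa1b fell from 14820 ± 1649 to 1023 ± 225 (-3.87 ± 0.19) and from 15890 ± 1905 to 560 ± 294 (-4.92 ± 0.33). The pair are close copies that can share reads, so how the fall divides between them is uncertain. The mitochondrial ribosomal RNA mt-Rnr2 fell from 393200 ± 128200 to 47460 ± 6986, with Rpph1, which shares 73% of its exons with another gene, mt-Tl1, Grid1, Sez6l, Mfsd7a, Haus3 and Ret also lower.

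Of 16 genes of the dissociation response 9 rose and 2 fell in Adipo (13 and 2 adjusted over the list alone). Their median log2 fold change was 2.34 (camera adjusted p = 7.74e-08, adjusted p = 0.590 with an estimated correlation). Junb (2.43 ± 0.19 SE) and Fos (2.24 ± 0.21) rose, and the members that fell were Hspa1a and Hspa1b. Of 21 genes of the early cAMP response 5 rose (13 adjusted over the list alone), with a median of 1.30 (camera adjusted p = 7.74e-08, adjusted p = 0.306 with an estimated correlation; fry adjusted p = 0.0171). That list shares Fos, Fosb, Junb, Atf3, Dusp1 and Nr4a1 with the dissociation list. Of 18 endothelial markers 3 rose and 17 passed adjusted over the list alone, with a median of 2.82 (camera adjusted p = 2.64e-12, adjusted p = 0.730 with an estimated correlation). Sox17 rose from 49.9 ± 13.04 to 564 ± 253 (SD, n = 3 and 2). Ptprb (2.94 ± 0.28) and Robo4 (2.82 ± 0.27) rose too. The mean log2 level of the endothelial markers was 11.7 and 10.7 in the libraries labelled knockout 1 and 2 and 7.99 to 8.87 in wild type. In the Epi tissue libraries, a table normalised separately, it was 12.5 to 12.8. All 11 mesothelial markers were higher, 0 over all genes and 7 adjusted over the list alone, with a median of 2.29 (camera adjusted p = 3.39e-05, adjusted p = 0.730 with an estimated correlation). Of 33 cytokine and NF-kB genes 4 rose (7 adjusted over the list alone), Nfkbiz, the chemokine Cxcl1 (2.61 ± 0.16), Nfkbia (1.81 ± 0.20) and Tnfaip3 (2.25 ± 0.29). Irf1 (3.17 ± 0.16) rose from the interferon list. All 18 adipocyte identity genes were measured and 0 passed, over all genes or adjusted over the list alone, with a median of 0.09. Nuclear-encoded OXPHOS genes were lower for 66 of 73 and higher for 7, whereas all 73 were higher in Epi tissue. Of these 0 passed over all genes or adjusted over the list alone, with a median of -0.15. Camera called the list lower (adjusted p = 0.00161, but adjusted p = 0.904 with an estimated correlation). Limma called 90 genes in all, 143 after TMM scaling and 0 without trend and robust fitting, edgeR 142 (88 shared) and DESeq2 1714. Limma called 3, 13 and 718 without the library labelled wild type 1, 2 and 3. It called 4 without that labelled knockout 1 and 79 without that labelled knockout 2, of which 36 rose and 43 fell and 32 were shared with the 90. Both leave 1 library in the arm, assumed to vary like the others. The library labelled wild type 3 stood apart, at a mean log2 level of 8.91 for cytokine and NF-kB genes against 6.94 and 6.84 in the other wild-type libraries and 9.09 and 8.35 in those labelled knockout. Its macrophage markers, at 9.71, lay above both libraries labelled knockout. The direction follows the labels, though the short share of Gps2 lay in the wild-type range in the library labelled knockout 2.

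The effect of genotype in adipocytes was set against that in the tissue of the Epi table in 1 fit over both. By the labels it differed for 217 of 16944 genes, 212 of them with a larger rise in adipocytes (limma, Benjamini-Hochberg). Irf1 differed by 3.22 ± 0.22 on the log2 scale (SE; adjusted p = 0.000497 by limma), with fold changes of 3.17 in adipocytes and -0.06 in tissue. Arid5a, Rnd1, Nfkbiz and Klf2, an endothelial and T cell transcription factor, differed by 3.46 ± 0.27, 4.95 ± 0.41, 4.08 ± 0.35 and 3.44 ± 0.34. Hspa1b differed by -5.25 ± 0.43 and Hspa1a by -4.49 ± 0.35, mt-Rnr2 by -3.33 ± 0.52 and the chaperone cofactor Bag3 by -0.84 ± 0.16. With the replicate number as a block, which pairs tissue and adipocytes, limma called 212 genes, 152 of them shared with the 217, and Bag3 did not pass. Without 1 of the Adipo libraries the count was 107, 85 and 614 (wild type 1, 2 and 3) and 33 and 335 (knockout 1 and 2). Without 1 of the Epi libraries it was 48, 33 and 45 (wild type) and 117, 120 and 37 (knockout). It was 13 without the libraries labelled Epi knockout 2 and 3, which leaves 1 library in that arm. It was 47 without trend and robust fitting, 190 by edgeR (182 shared) and 855 by DESeq2.

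Whether the effect of genotype differed with diet was tested in the same way among the intra-abdominal tissue tables, which differ also in age or sequencing. Between HFD and CD 0 of 15046 genes differed by limma (2595 at an unadjusted p under 0.05; edgeR 0, DESeq2 749). Between Epi and CD 0 of 17278 differed (1346; edgeR 0, DESeq2 577) and between Epi and HFD 0 of 16474 (2588; edgeR 0, DESeq2 847). No difference between diets passed this test, which does not show that the effects were equal. Kcnk3, for example, had a log2 fold change of -2.58 ± 0.25 SE in HFD, -1.47 ± 0.39 in CD and -1.32 ± 0.37 in Epi. The HFD against CD count was 15, 10, 6 and 1213 without the library labelled HFD wild type 1, CD wild type 2, CD wild type 3 and CD knockout 3. For Epi against CD the count was 15 or 226 without the library labelled Epi knockout 1 or CD knockout 3. For Epi against HFD it was 133 without Epi knockout 1 and 2 without Epi knockout 2. Leaving out CD knockout 3 kept only the nearly alike CD knockout 1 and 2, both with epididymis and testis markers. Of the 1213 and 226 genes, 1106 and 216 had a negative difference. The spread between such libraries may be too small, so these counts cannot show a difference between diets.

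In inguinal fat of the beta-adrenergic series (BA table), 4 genes rose and 0 fell in the libraries labelled knockout. Prss35, a protease-like secreted protein (chromosome 9, 86743649 to 86758443), rose from 25.9 ± 18.4 to 340 ± 131 normalised reads (SD, n = 4 and 4; log2 fold change 3.88 ± 0.48 SE). Tmem86a, a lysoplasmalogenase (chromosome 7, 47050601 to 47054777), rose from 169 ± 6.39 to 354 ± 60.8 (1.05 ± 0.13) and Fam69b from 685 ± 63.5 to 1385 ± 152 (1.01 ± 0.12). Each of the 3 had an adjusted p of 0.0363 by limma with Benjamini-Hochberg adjustment over 12418 genes. After TMM scaling, without trend and robust moderation or without a filter 0 of the 3 passed, and 1 passed with the replicate number as a block, all in the same direction. The 4th, Dock3, lay below the level set for named genes and was named after its values were seen: it rose from 2.34 ± 0.97 to 37.7 ± 15.3 (3.48 ± 0.37). Cyp51, the sterol demethylase of cholesterol synthesis, was 2634 ± 1212 and 12180 ± 6762 (2.19 ± 0.38) and did not pass (adjusted p = 0.0809 by limma).

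Of 22 cholesterol synthesis genes 19 were higher in BA, 0 passed over all genes and 8 passed adjusted over the list alone. Their median log2 fold change was 0.46 (camera adjusted p = 4.06e-06, but adjusted p = 0.632 with an estimated correlation). Adipocyte identity genes were higher for 16 of 18, with 0 passing either way and a median of 0.43 (camera adjusted p = 9.45e-06, adjusted p = 0.480 with an estimated correlation), Cebpa among them (0.63 ± 0.18 SE). Thermogenic genes were lower for 22 of 25, with 0 passing either way and a median of -0.66 (camera adjusted p = 3.62e-05, adjusted p = 0.754 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial genes, was 212 ± 127 in wild type and 107 ± 21.8 in the libraries labelled knockout (SD, n = 4 and 4), and S100b had a log2 fold change of -1.02 ± 0.37. Their mean log2 level ranged from 8.47 to 10.6 in wild type and from 7.99 to 9.26 in the libraries labelled knockout. Nuclear-encoded OXPHOS genes were lower for 54 of 73 and higher for 19, with a median of -0.08 and 0 passing either way. Camera called that list lower (adjusted p = 0.0452, but adjusted p = 0.934 with an estimated correlation). Cell cycle genes were higher for 18 of 19 (median 0.32, camera adjusted p = 3.62e-05, adjusted p = 0.480 with an estimated correlation). T cell markers were higher for 8 of 8 (median 0.61, camera adjusted p = 0.00139, adjusted p = 0.632 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Plin2, which coats lipid droplets (0.96 ± 0.24), Adrb1 (-1.45 ± 0.37), Angptl4 (0.91 ± 0.21), Fabp5 (0.74 ± 0.20) and Itgax (0.82 ± 0.25) passed adjusted over their list alone and not over all genes. Skeletal muscle markers had a mean log2 level of 7.87 in the library labelled knockout 3 and 7.82 in that labelled wild type 2, against 2.25 to 4.15 in the other 6. The 4 calls became 0 without the library labelled wild type 1, 2 or 4 or knockout 3 or 4, 1 without knockout 2, 9 without knockout 1 and 0 without the 2 libraries with muscle genes. EdgeR called 4 (3 shared) and DESeq2 267. Of 10914 genes with a mean above 50 in every other table, 506 have no values in BA and were not analysed there.

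**Figure D3:**
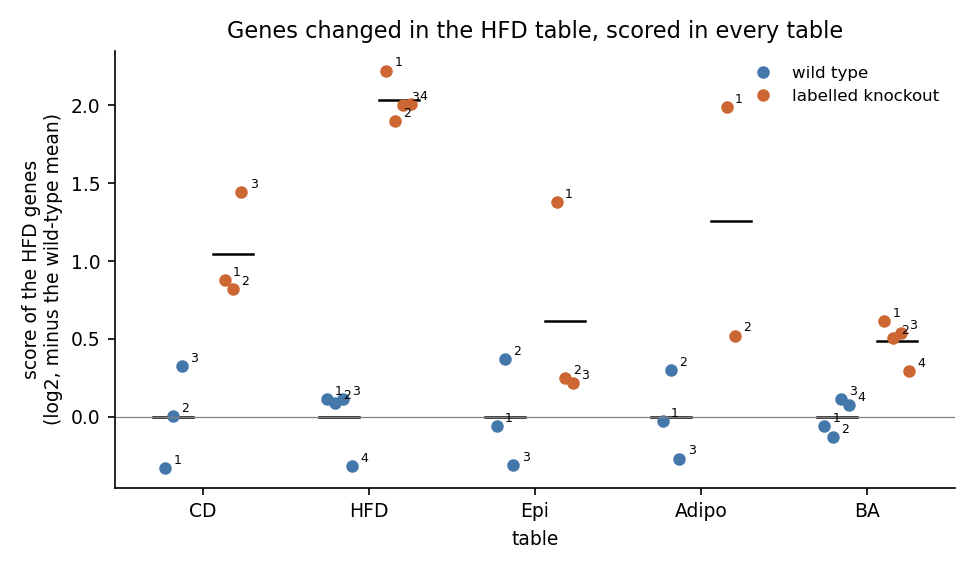
Score of the genes called in HFD, per replicate in the 5 tables. It is the mean log2 level of those that rose minus that of those that fell, relative to the wild-type mean of each table. Points are replicates and black lines are group means; in BA the libraries labelled knockout lie between 0.292 and 0.613 and wild type reaches 0.115, and the HFD column is circular.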

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

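The tests of other splits of the samples and of the explanations in this part were all chosen after the results were seen; the far samples and the differences between tables were found by rules fixed beforehand. Of 198 values tested for a sample far from the others of its group, 13 lay beyond Dixon's 95% critical value for groups of 4, where 9.9 are expected by chance.

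In HFD the library labelled wild type 1 stood apart for Serpina3b (gap over range 0.927; 7.08 against 6.24 to 6.30 on the log2 scale). The library labelled HFD knockout 1 stood apart for B cell markers (0.858; mean log2 level 6.22 against 4.03 to 4.34). That labelled HFD knockout 2 stood apart for extracellular matrix genes (0.867; 10.9 against 11.5 to 11.6), stromal markers (0.845), Kcnk3 (0.938) and Oxtr (0.831). Lipogenic genes were lower in that labelled HFD knockout 4 (0.836). In BA the libraries labelled wild type 4, 2 and 1 stood apart for LXR targets (0.932), cell cycle genes (0.908) and the dissociation response (0.893). Mast cell markers were higher in the library labelled BA knockout 4 (0.838). In that labelled BA knockout 3 muscle markers were higher (0.867; 7.87 against 2.32 to 3.06) and thermogenic genes lower (0.889; 7.99 against 9.12 to 9.26).

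Adipocytes and tissue differed in the effect of the genotype label by the interaction test for Irf1 (3.22 on the log2 scale), Arid5a (3.46), Rnd1 (4.95), Nfkbiz (4.08), Klf2 (3.44), Hspa1a (-4.49), Hspa1b (-5.25), mt-Rnr2 (-3.33) and Bag3 (-0.84). The Adipo libraries labelled knockout also had a higher dissociation response (mean log2 level 13.6 and 13.9 against 12.1 to 12.4 in wild type). Their endothelial markers stood at 11.7 and 10.7 against 7.99 to 8.87. In Epi the groups overlapped in both. An effect of genotype thus cannot be told apart here from differences in preparation or cell content of the adipocyte libraries.

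The 486 genes called in HFD were weighed first. Strain variants kept around the targeted gene would place called genes near Gps2, but 9 lay within 10 Mb of it where 10.2 are expected (Fisher's exact two-sided p = 0.872). Cells of other types in the libraries labelled wild type 1 and knockout 1 are argued against as the whole source by the 448 genes called without both. A hypothesis is that part of the pattern is an effect of the knockout that other samples share, since the HFD genes scored higher in all 4 BA libraries labelled knockout than in any BA wild-type library (exact two-sided permutation p = 0.0286). The share of those genes with the HFD direction in BA, 68.4%, was below the 76.4% reached by another labelling of the same samples, so this stays open.

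The libraries labelled Epi knockout 2 and 3 and Adipo knockout 2 lay near wild type in their short share of Gps2, while that labelled HFD wild type 4 lay in the range of the libraries labelled knockout. Whether epididymal RNA hid the HFD genes stays open. The CD libraries that also carry it scored 0.878 and 0.821, against at most 0.323 in CD wild type. That labelled CD knockout 3, which lacks it, scored 1.44. These CD libraries had 11 of 17 markers at 50 normalised reads or more, against 16 and 14 in Epi knockout 2 and 3. They were also nearly alike, so they cannot decide the question. A wrong label or no deletion may account for Epi knockout 2 and 3, which scored 0.249 and 0.216 against up to 0.370 in wild type. The library labelled Adipo knockout 2 scored 0.521 against up to 0.299. All 3 Epi libraries labelled knockout lay below wild type in cell cycle genes (mean log2 level 7.65 to 8.14 against 8.60 to 9.38). They did so in extracellular matrix genes too, but overlapped wild type in OXPHOS and adipocyte identity genes. These lists were picked after their values were seen, so the question of a wrong label stays open. RNA of cells other than adipocytes stays open too, since the adipocytes labelled knockout 2, with a share of 47.9%, are 1 library and part of the pattern. Endothelial RNA did not go with a high share there: the adipocytes labelled knockout 1 had more of it (mean log2 level 11.7 against 10.7) and a share of 31.3%.

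Epididymis and testis markers stood in 2 CD and 2 Epi libraries labelled knockout. The knockout itself is argued against as the cause by the library labelled CD knockout 3, which lay 2.54 below the highest CD wild-type library (difference -2.54 on the log2 scale). Epididymal tissue taken with the fat is a candidate explanation, since at least 11 of 17 markers reached 50 normalised reads in each of the 4 libraries, with Adam7 at 29590, 28660, 21470 and 5019. Some markers were also present in wild type, 6 of 17 in Epi wild type 1 and 2 in CD wild type 2.

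Among the 35 splits of the HFD samples into groups of 4, 1 gave as many genes as the 486 called, the real split itself, and the highest other gave 0; in BA likewise 1 of 35, with 4 genes and 0. No other split reached either count, but a test of 35 splits chosen after the results were seen cannot exclude chance. Nor can chance be excluded for the lists. There 18 of 35 splits gave at least the 12 lists of HFD (highest other 25). In BA 5 of 35 gave at least 15 lists (highest other 17). The splits were too few for a share under 0.05 in the other tables. CD had 0 genes with a highest other of 1440 (10 of 10 splits as large) and 21 lists against 20 (1 of 10). Epi had 0 genes against 1 (10 of 10) and 13 lists against 17 (5 of 10), and Adipo 90 genes against 0 (1 of 10) and 11 lists against 18 (6 of 10). The CD split with 1440 genes set wild type 2 and the libraries labelled knockout 1 and 2 against the others, which points to a structure of the samples. The same 3 libraries stood apart in mammary and epithelial markers (9.09 to 9.18 against at most 3.62). For Adipo against Epi 217 genes stood against 0 (1 of 10). For HFD against CD, Epi against CD and Epi against HFD the real count by limma was 0, at or below that of all 100 splits drawn for each, with a highest other of 2327, 598 and 79.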

How the results depend on the processing

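The edgeR and DESeq2 tests on recovered reads, summed isoforms and the left-out pairs of libraries were chosen after the data were seen; the others were planned. Of the values that answer a comparison 214 kept their side of the threshold or stayed within 1.5 times, 36 became stronger and 49 weaker. Of the named genes' values 7827 were the same, 230 stronger, 450 weaker and 90 moved, and 0 reversed. A reversal was counted only where the gene passed in the main or the alternative fit. The 0 thus does not cover changes of sign in genes that passed in neither. The cause was not tested except where fewer samples or genes explain a count. The highest counts below for CD, HFD against CD and Epi against CD left out the library labelled CD knockout 3. That kept only the nearly alike CD knockout 1 and 2, so these counts may be too high. Leaving out 1 replicate gave counts of 0 to 648 genes in CD, 126 to 1178 in HFD, 0 to 22 in Epi, 3 to 718 in Adipo and 0 to 9 in BA, and 0 to 1213 for HFD against CD, 0 to 226 for Epi against CD, 0 to 133 for Epi against HFD and 33 to 614 for Adipo against Epi; CD lists ranged from 13 to 20. DESeq2 called 918 genes in CD, 1538 in HFD, 528 in Epi, 1714 in Adipo, 267 in BA, 749 for HFD against CD, 577 for Epi against CD, 847 for Epi against HFD and 855 for Adipo against Epi, and edgeR 142 in Adipo. Without trend and robust moderation limma called 1 gene in CD, 0 in Adipo, 2 in BA and 47 for Adipo against Epi; without a filter it called 391 in Adipo, 2 in BA, 3 for HFD against CD and 135 for Adipo against Epi. TMM scaling gave 143 in Adipo and 1 in BA, a size threshold of 1 gave 167 in HFD, and summed isoforms gave 7 in BA. The leading numbers 1, 2, 3 and 4 alone gave 1, 0, 9 and 8 genes in BA. Without wild type 2 and knockout 3, BA gave 0 genes and 8 lists, and a minimum of 50 gave 9 BA lists. Without HFD wild type 1 and knockout 1, HFD against CD gave 2; without Epi knockout 2 and 3, Epi against HFD gave 4 and Adipo against Epi 13. With an estimated correlation camera called 0 lists in CD, 0 in HFD, 0 in Epi, 0 in Adipo and 0 in BA, and fry 3 in CD, 0 in HFD, 0 in Epi, 2 in Adipo and 0 in BA.

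With the replicate number as a block limma called 272 genes in HFD (244 shared), 1411 in Adipo, 0 in CD, 0 in Epi and 4 in BA, but within these tables the samples share only a number: 2 of 3 same-numbered pairs deviated together above 0.1 in CD, 0 of 4 in HFD, 1 of 3 in Epi, 1 of 2 in Adipo and 1 of 4 in BA, and 4 of 6, 0 of 8, 2 of 6, 2 of 5 and 2 of 8 samples correlated best with their own number. Where the numbers pair Epi and Adipo samples, the block gave 212 genes, 152 of them shared with the 217 without it, and of the 9 genes named for that comparison only Bag3 no longer passed. Depth limits low genes: the 3 libraries without recovered reads were left out of the tests on reads.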

Other observations

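The comparison of the HFD genes with the other tables was chosen after the results were seen. Of the 20 genes with the largest rise or fall in HFD, 18 of 20 had the same direction in CD and 13 an unadjusted p under 0.05, 18 of 20 and 11 in Adipo, 15 of 20 and 6 in Epi, and 12 of 16 and 4 in BA. Over all HFD genes the share with the HFD direction was 76.5% in CD, where the highest other labelling of the same samples gave 71.5%. It was 78.1% in Adipo, 68.9% in Epi and 68.4% in BA, below the 88.5%, 81.3% and 76.4% of another labelling. The Wnt antagonist Sfrp5 had log2 fold changes of -5.40 ± 0.98 SE in CD, -2.47 ± 0.37 in Epi and -3.54 ± 0.98 in Adipo, and the actin-binding Synpo2 of -3.40 ± 0.67, -2.19 ± 0.48 and -2.48 ± 0.86, whereas in BA they were 0.02 ± 0.44 and -0.14 ± 0.22. Mogat2, an enzyme of triglyceride synthesis, was 2.53 ± 0.40 in CD and 2.37 ± 0.38 in BA but -1.18 ± 0.44 in Adipo, and Pnpla5 3.45 ± 0.79 in CD and 1.45 ± 0.23 in BA. The fold changes given here for these 4 genes in the other tables did not pass over all genes by limma with Benjamini-Hochberg adjustment.

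The score of all HFD genes is the mean log2 level of those that rose in HFD minus that of those that fell. It is taken relative to the wild-type mean of each table and adds rise and fall, so it is not a mean change per gene. The score was 0.878, 0.821 and 1.44 in the CD libraries labelled knockout 1, 2 and 3 and at most 0.323 in wild type. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allow. In BA the score ranged from 0.292 to 0.613 in the libraries labelled knockout and reached 0.115 in wild type. In Epi it was 1.38, 0.249 and 0.216 in the libraries labelled knockout 1, 2 and 3 (exact permutation p = 0.3). In Adipo it was 1.99 and 0.521, both above the highest wild-type score of 0.299 (n = 3 and 2, exact permutation p = 0.2). In HFD itself the score is circular.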
